A study of Mus musculus with 8 samples.

How the data were processed

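Ribosome footprint libraries were made from cultured bone marrow cells of wild-type mice and of mice lacking Dnmt2 (gene symbol Trdmt1), an RNA cytosine methyltransferase that acts on certain tRNAs. The mice were of the C57BL/6 strain at postnatal day 8. Per the labels' protocols, mononuclear cells were grown with thrombopoietin, FLT3 ligand and stem cell factor, and the cells in suspension were collected apart from the attached stroma. Elongating ribosomes were held on their mRNAs with cycloheximide, the lysate was digested with RNase I, monosomes were taken from a sucrose gradient, and fragments of 28 to 31 nucleotides were made into small RNA libraries.

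The authors deposited one table of raw whole-number counts, with 20154 UCSC known-gene IDs and 8 columns of libraries, per the file headers. Reads were aligned with Bowtie to the mouse build mm9, per the submitters' processing notes. The Bowtie version, the counting tool, the transcript set, the strand setting and the treatment of reads with several matches are not given in the sources used here. A count therefore holds all footprints assigned to one ID, with no correction for mRNA level. No matched RNA libraries were analysed here, so differences in footprint counts combine mRNA abundance and translation. Reads shared between IDs of near-identical sequence could be split or lost by the counting.

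The table does not pair its IDs with gene names. Of its 20154 IDs, 0 were found in the reference gene table supplied with the data, which describes build GRCm38. The sources used here held no list that pairs UCSC known-gene IDs with gene symbols, so no gene was named. This is a limit of those sources and not of the IDs. The targeted gene was therefore not looked up as a check of the labels. The marker and pathway lists fixed before the data were examined were not tested. For the same reason no coordinates or annotations are given.

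Of the columns, 6 matched one sample each by its description. The other 2 columns carried the same header, which was the description of both knockout stroma samples. They were used as 2 replicates of that group without a replicate number and are called library a and library b, in names only. Nothing in the labels says whether replicates came from separate animals or cultures, so p-values measure only the spread between these libraries, which may be technical.

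Counts were tested with edgeR 4.0.16 in R 4.3.3. IDs were kept by filterByExpr with its default minimum count of 10, which left 10157 IDs that held 99.8% of each library's counts. No count in any library was present for 6101 IDs. Totals per library lay between 1713729 and 4025780 counts. Library sizes were scaled by TMM, and 1 quasi-likelihood model with 4 group means was fitted to all 8 libraries, so that the groups shared one estimate of spread. The 5 contrasts were knockout against wild type in suspension cells and in stroma cells, their interaction, and stroma against suspension in each genotype. P-values were adjusted by the Benjamini-Hochberg method within each contrast and called at 0.05. Standard errors (SE) of log2 fold changes were derived from the quasi-likelihood F statistic, and 95% intervals from these and the model's degrees of freedom. The fold changes carry a prior count and the F statistic does not. The SE and intervals are therefore approximate, above all for small changes or few counts, and can differ from the test's own p-value. CPM values are counts scaled to a common TMM-adjusted library size. Fold changes are those of the edgeR fit, with its default prior count. The design and the alternatives were set before the data were examined, except those named below as added.

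Pairs of libraries were compared by a chi-square test of their counts over the tested IDs, divided by its degrees of freedom, where 1 stands for sampling noise alone, and by correlations of log2 CPM across IDs. IDs are not independent replicates. Counting intervals of ratios are exact (Clopper-Pearson) and cover counting error only, since the sources used here name no molecular identifiers and PCR copies are not independent molecules.

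The rule for named features took the 10 IDs with the largest rise and the 10 with the largest fall in log2 fold change in each contrast (5 and 5 for the interaction and for the fractions of the knockout). They had to be past the threshold, with libraries of the groups not overlapping and a mean of 30 or more counts in the higher group. In contrasts with fewer than 5 calls, the rule added the 5 IDs of lowest unadjusted p, and it also took Dnmt2 and members of the gene lists. Because the sources used here gave no names for the IDs, this was limited afterwards to 2 IDs in each direction, from stroma against suspension in wild type. For each genotype contrast within a fraction, the 1 ID of lowest p is described without its ID.

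The labels do not state what a replicate number marks, so the main model has no block. A block by number could be fitted only to the 6 numbered libraries, for the genotypes in suspension and for the fractions in wild type.

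The test was run on simulated negative binomial counts with the means over all libraries, library sizes and dispersions of the 10157 IDs, in which 100 IDs were changed 2-fold and 100 IDs 4-fold. For knockout against wild type in suspension cells, 4% of the 2-fold and 79% of the 4-fold changes were recovered. For stroma cells, 9% and 64% were recovered, and for the interaction 1% and 11%. For stroma against suspension, the shares were 11% and 73% in wild type and 8% and 68% in the knockout. False calls among the unchanged IDs were 6, 7, 4, 5 and 3 in the same order. The simulated libraries shared no profile by replicate number, so these shares need not hold for the real libraries. Far fewer IDs were changed than the 1556 called between the real fractions in wild type. The adjusted threshold is stricter when few IDs change, so the shares for stroma against suspension can be too low. In suspension cells, 4.63% of the unchanged simulated IDs had an unadjusted p under 0.05, against 64 of 10157 real IDs. Alternatives tried were other scaling factors, other filters, DESeq2 1.42.0, limma 3.58.1 with voom, fits of only the groups compared, leaving out each library, blocks by number, and, added after the data were seen, the 6 numbered libraries without a block, contrasts averaged over both fractions or both genotypes, raw library sizes, 1 surrogate variable from sva 3.50.0, and the first principal component of the residuals as a covariate. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.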

Results

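Ribosome-protected mRNA fragments were counted in 8 libraries from cultured mouse bone marrow, in 4 groups of 2. The groups were wild-type suspension cells, Dnmt2 knockout suspension cells, wild-type stroma and Dnmt2 knockout stroma. Suspension cells are the haematopoietic cells that float free in the culture, and stroma cells are those attached to the dish. The suspension libraries held 4025780 and 2742492 counts in wild type, and 3586961 and 1713729 in the knockout. The stroma libraries held 2151743 and 3962230 counts in wild type, and 1864155 and 3154238 in the knockout. Each library had at least 1 count for between 11664 and 12369 of the 20154 UCSC known-gene IDs. The 10 most abundant IDs took 10.1% to 11.3% of the counts in suspension libraries and 14.3% to 16.1% in stroma libraries. The table gives IDs without gene names, so features are described below as IDs and as groups of IDs, and the level of Dnmt2 itself was not analysed here.

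The attached and suspended fractions differed most. In suspension, libraries of the 2 genotypes lay close together only within one replicate number. The first principal component of log2 CPM held 66.7% of the variance and separated the 4 suspension libraries from the 4 stroma libraries. The second held 17.3% and separated replicate 1 from replicate 2 in each of the 3 groups with numbered libraries. The 2 unnumbered knockout stroma libraries also lay apart on it, at 18.9 for library a and -18.0 for library b. Neither separated the genotypes in stroma. In suspension, the knockout libraries lay beyond the wild-type libraries on the first component, at -52.0 and -49.3 against -42.1 and -47.5, and the second did not separate the genotypes.

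**Figure D1:**
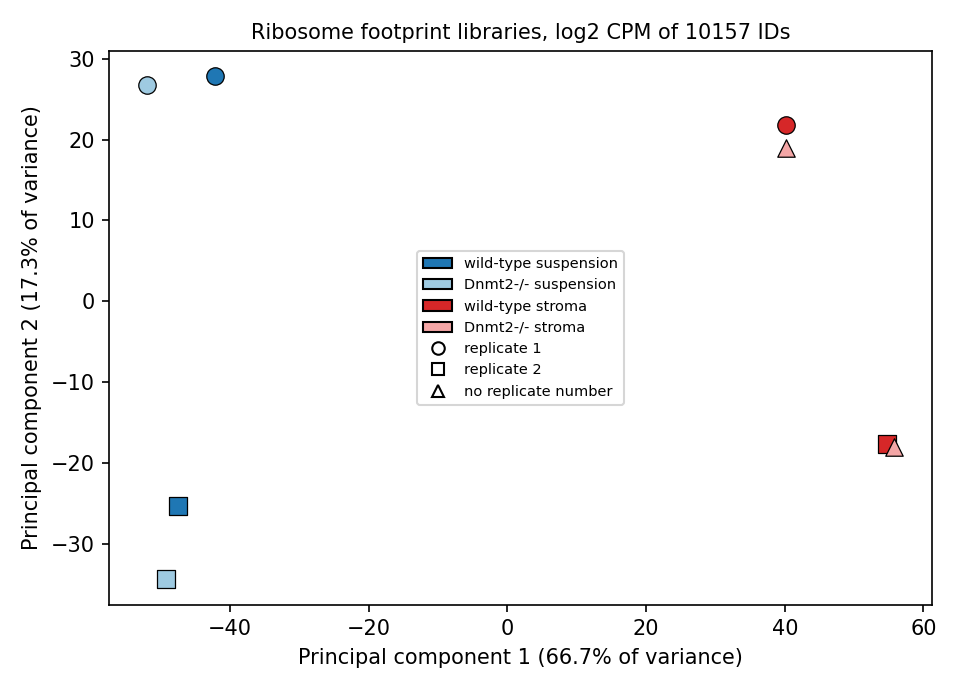
Each point is 1 footprint library on the first and second principal components of log2 CPM over 10157 IDs; colour gives the group and marker shape the replicate number. Suspension libraries lie at the left (-52.0 to -42.1) and stroma libraries at the right (40.1 to 55.8), and replicates 1 lie above replicates 2.

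In suspension cells, replicates of one group differed far more than wild-type and knockout libraries of one replicate number. There the chi-square per degree of freedom between genotypes was 4.41 for replicate 1 and 2.43 for replicate 2. This value grows with library depth, so pairs of unlike depth are not strictly comparable by it. Pearson's r of log2 CPM for the same pairs was 0.986 and 0.979. Between the replicates of one group, the chi-square per degree of freedom was 22.7 in wild-type suspension, 20.7 in knockout suspension, 14.5 in wild-type stroma and 12.3 in knockout stroma. Of the 2 knockout stroma libraries, library a differed from wild-type stroma replicate 1 by 1.62 and from replicate 2 by 12.3. Library b differed from them by 14.6 and 1.85. Suspension pairs of other genotype and other number differed by 20.8 and 23.5. Pairs from different fractions differed by 42.2 to 134. Every pair exceeded the value of 1 that sampling noise alone would give, so no pair differed by sampling noise alone. Libraries prepared apart from one source can also exceed it, so these values do not exclude a shared source. Pearson's r of log2 CPM across IDs averaged 0.955 between replicates of one group.

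**Figure D2:**
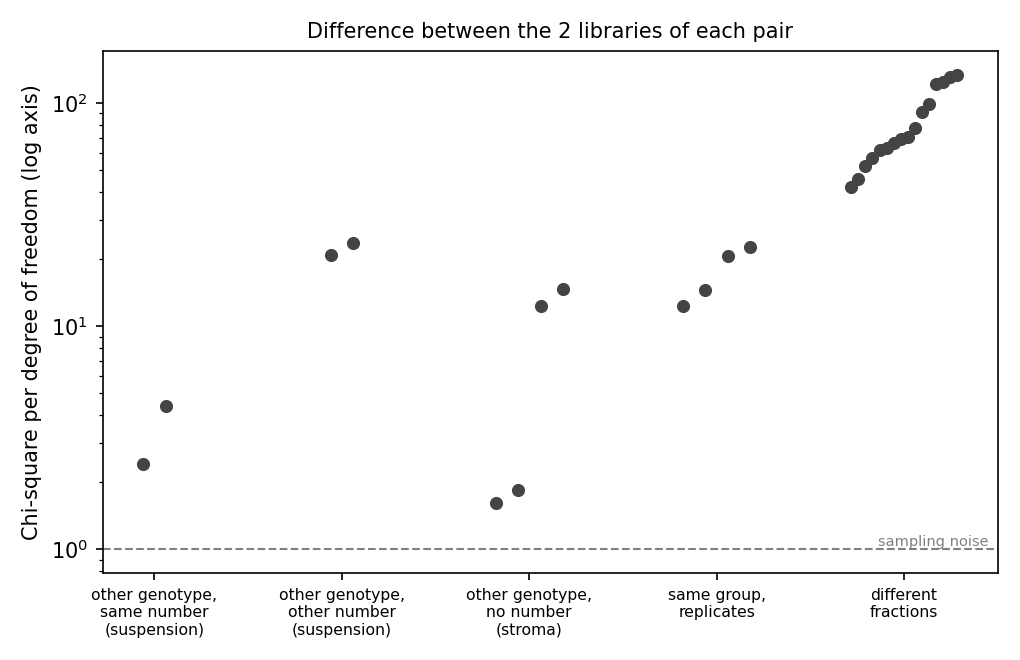
Each point is 1 of the 28 pairs of libraries, and the vertical log axis gives the chi-square per degree of freedom over the tested IDs, with the dashed line at the value for sampling noise. Suspension pairs of other genotype and same number (2.43 and 4.41) lie below all replicate pairs of one group (12.3 to 22.7).

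The first comparison asked whether loss of Dnmt2 changed footprint levels in suspension cells. No ID was called: 0 of 10157 had an adjusted p under 0.05 in edgeR's quasi-likelihood test, in either direction. At an unadjusted p under 0.05 there were 64 IDs, against 508 that uniformly spread p-values would give. DESeq2's Wald test and limma with voom also called 0, with 18 and 74 IDs at an unadjusted p under 0.05. The ID with the lowest p had 59 and 40 counts in wild type and 109 and 47 in the knockout, a log2 fold change of 1.01 ± 0.25 (SE), with an adjusted p of 1.00 in edgeR's test. The median absolute log2 fold change over all tested IDs was 0.14, with a median SE of 0.33.

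The size of change that these suspension libraries leave open can be given approximately for each ID. For 5754 IDs (56.7%), the 95% interval of the fold change lay within 2-fold in both directions, each taken by itself. For the other IDs this interval reached a change of 2-fold or more. The intervals come from a model without replicate number, so the difference between numbers widens them and raises the p-values. Taken within one replicate number, 158 IDs differed by more than 2-fold between the genotypes for replicate 1 and 332 for replicate 2. Of these, 16 did so in the same direction for both numbers and 7 in opposite directions. Across IDs, the knockout minus wild type differences of the 2 numbers correlated with a Pearson's r of 0.0836 and a Spearman's rho of 0.0715.

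The same question was put to the attached stroma cells. No ID was called there either: 0 of 10157 were called by edgeR's quasi-likelihood test. At an unadjusted p under 0.05 there were 43, against 508 that uniformly spread p-values would give. Here too, the model had no replicate number. Replicates within the stroma groups differed by 14.5 and 12.3 in chi-square per degree of freedom. The closest stroma pairs of other genotype differed by 1.62 and 1.85. Such spread within groups raises the p-values and widens the intervals. DESeq2 and limma with voom also called 0, with 6 and 39 IDs at an unadjusted p under 0.05. The ID with the lowest p had 1 and 5 counts in wild type and 11 and 13 in the knockout, a log2 fold change of 2.32 ± 0.61 (SE), with an adjusted p of 1.00 in edgeR's test. The median absolute log2 fold change was 0.14, and for 5613 IDs (55.3%) the 95% interval lay within 2-fold in both directions. Values within one replicate number could not be given, because the knockout stroma columns share one header and cannot be matched to a replicate number.

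Whether the genotype difference depended on the fraction was tested as an interaction. No ID was called by edgeR's quasi-likelihood test among 10157. An unadjusted p under 0.05 was reached by 46 IDs, against 508 for uniformly spread p-values. The difference between replicates of one group raises these p-values as well. DESeq2 and limma with voom also called 0, with 8 and 48 IDs at that level. For 2475 IDs (24.4%) the 95% interval of this difference lay within 2-fold. The genotype log2 fold changes of suspension and stroma, which share no library, correlated across IDs with a Pearson's r of 0.0565 and a Spearman's rho of 0.0622.

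Stroma and suspension cells of wild-type mice differed in a large set of IDs. In stroma, 874 IDs rose and 682 fell against suspension cells, together 1556 or 15.3% of those tested, at an adjusted p under 0.05 in edgeR's quasi-likelihood test. The median absolute log2 change of the called IDs was 1.67, and 312 were more than 4-fold higher and 256 more than 4-fold lower. The number of calls and their balance depended on single libraries. Without wild-type stroma replicate 2 there were 345 calls (259 higher and 86 lower in stroma), and without wild-type suspension replicate 2 there were 777 (493 and 284). Without wild-type suspension replicate 1 there were 840, of which more were lower (476) than higher (364). Other choices raised the number, to 2367 without a low-count filter and further with replicate number in the model. DESeq2 called 1436 IDs and limma with voom 1563. Within one number, the stroma minus suspension differences of replicates 1 and 2 correlated across IDs with a Pearson's r of 0.802 and a Spearman's rho of 0.739. More than 2-fold differences were shown by 2073 IDs for replicate 1 and 2614 for replicate 2, of which 1521 went in the same direction for both and 9 in opposite directions. Stroma-higher IDs made up 56.2% of the calls with TMM scaling and 37.9% with raw library sizes, which moved the median log2 fold change of all tested IDs from -0.03 to -0.26. No ID (0) had a mean of 10 or more counts in the 4 stroma libraries and no count in the 4 suspension libraries. The reverse was shown by 1 ID, which is not among those named below.

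The IDs with the largest changes that met the naming rule were scarce in the lower fraction, which a choice by largest change favours. They were chosen on these same libraries, so their ratios tend to be too large. The counting intervals do not allow for that choice. The ID uc007boz.1 rose from 0.284 ± 0.083 CPM in suspension to 12.9 ± 6.4 CPM in stroma (SD, n = 2), with an adjusted p of 0.00869 in edgeR's test. Its counts summed over the libraries of each group were 2 and 80, which after scaling by the summed TMM-adjusted library sizes gave a ratio of 52.1, with a 95% counting interval of 14.0 to 437. The ID uc007mxh.1 rose from 0.514 ± 0.727 to 14.4 ± 12.1 CPM (SD, n = 2), with an adjusted p of 0.0275 in edgeR's test. Its summed counts were 3 and 95, which scaled in the same way gave a ratio of 41.2, with a counting interval of 13.7 to 203. The ID uc009gyq.2 fell from 16.6 ± 3.2 to 0.277 ± 0.391 CPM (SD, n = 2), with an adjusted p of 0.00319 in edgeR's test. The ID uc008wmr.1 fell from 17.4 ± 1.1 to 0.522 ± 0.044 CPM (SD, n = 2), with an adjusted p of 0.00304 in edgeR's test. Their summed counts in suspension and stroma were 126 and 2 for uc009gyq.2, and 127 and 3 for uc008wmr.1. Scaled in the same way, these gave ratios of suspension to stroma of 48.4 and 32.5, with counting intervals of 13.1 to 404 and 10.9 to 159.8. The call of uc007boz.1 was lost without wild-type stroma replicate 2 (adjusted p = 0.0593, edgeR), and over all its alternatives the adjusted p lay between 4.35e-13 and 0.0593. The call of uc007mxh.1 was lost without that library (0.220), without wild-type suspension replicate 1 (0.123), with DESeq2 (0.0739) and with limma (0.0858), over a range of 3.15e-13 to 0.220. Both other IDs kept their call under every alternative that was run. The fitted log2 change of uc007boz.1 was 5.39 with all libraries and 4.76 without wild-type stroma replicate 2. That of uc007mxh.1 was 5.02, against 3.71 without wild-type stroma replicate 2, 5.68 without wild-type stroma replicate 1, 3.81 without wild-type suspension replicate 1 and 8.46 without wild-type suspension replicate 2, which held all its wild-type suspension counts. That of uc009gyq.2 was -5.42, against -4.78 without wild-type stroma replicate 1 and -8.55 without wild-type stroma replicate 2, which held all its wild-type stroma counts. With no count left in one group, the fitted value depends on the prior count.

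The same comparison was made in the knockout. In knockout stroma, 896 IDs rose and 742 fell against knockout suspension cells, together 1638, by edgeR's quasi-likelihood test. The number was 386 without knockout stroma library b (271 higher and 115 lower), 927 without knockout stroma library a (601 and 326) and 917 without knockout suspension replicate 1 (420 and 497). It was 2398 without a low-count filter. DESeq2 called 1484 IDs and limma with voom 1506. Stroma-higher IDs made up 54.7% of the calls with TMM scaling and 37.2% with raw library sizes. Both genotypes called 736 IDs higher and 546 lower in stroma, where independent lists of these sizes would share 77.1 and 49.8. The lists came from one fit with one estimate of spread per ID, so they are not independent and these numbers are only a rough reference. No ID (0) was called in opposite directions. Of the 1556 wild-type calls, 1555 had the same sign in the knockout. The fraction log2 fold changes of the genotypes, which share no library, correlated across IDs with a Pearson's r of 0.911 and a Spearman's rho of 0.885. A further 630 IDs were called in 1 genotype, and 0 of them were called by the interaction test, with 18 at an unadjusted p under 0.05. In the knockout, the log2 changes were -4.92 for uc009gyq.2, -4.81 for uc008wmr.1 and 4.89 for uc007mxh.1, with adjusted p-values of 0.00367, 0.00230 and 0.0455 in edgeR's test. The log2 change of uc007boz.1 was 2.37 ± 0.78 (SE), with an adjusted p of 0.0735 in edgeR's test, and its interaction of -3.03 ± 1.39 (SE) had an adjusted p of 1.00.

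**Figure D3:**
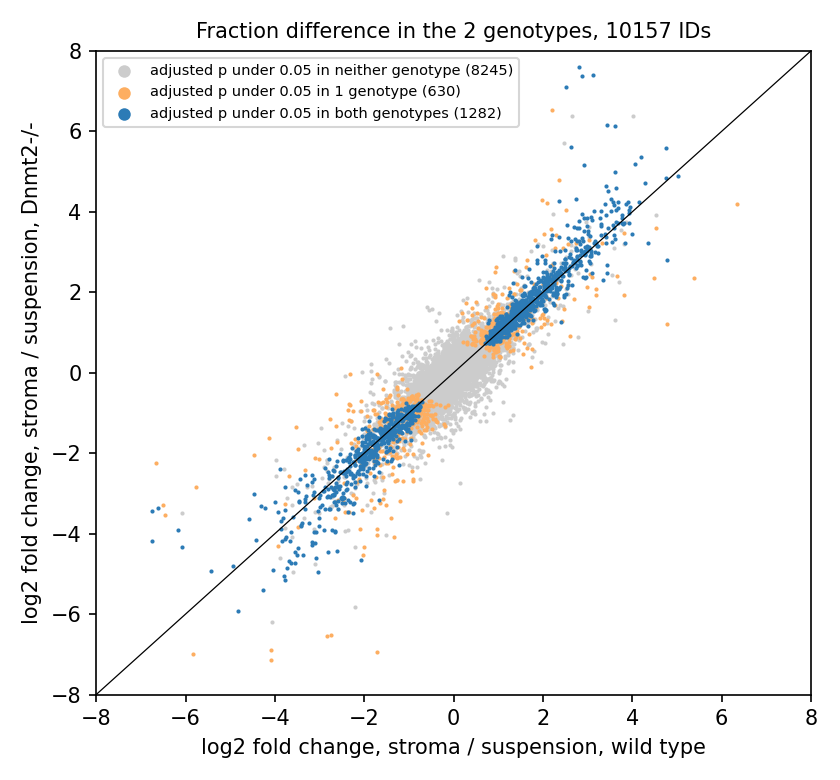
Each point is 1 of 10157 IDs, with its log2 fold change of stroma over suspension in wild type (horizontal) and in the knockout (vertical); colour gives whether the adjusted p was under 0.05 in both genotypes (1282 IDs), in 1 (630) or in neither (8245), and the line marks equal change. The points lie along the line, with a Pearson's r of 0.911.

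The IDs called in both genotypes took a different share of the footprints in each fraction. The 736 stroma-higher IDs held 28.4% ± 3.6 of the counts in wild-type stroma and 28.8% ± 3.8 in knockout stroma. They held 8.33% ± 0.42 in wild-type suspension and 8.08% ± 1.39 in knockout suspension (SD, n = 2 each). The 546 stroma-lower IDs held 3.57% ± 0.71 and 3.64% ± 0.68 of the stroma counts, and 15.2% ± 2.2 and 16.0% ± 1.2 of the suspension counts, in wild type and knockout. These IDs were chosen on the same libraries, so the shares describe the size of the difference and are not independent evidence of it. The group means of the genotypes differed by less than the SD between replicates, which includes the difference between replicate numbers. Within one number, the stroma-lower IDs held 13.6% of the counts in wild-type and 15.2% in knockout suspension for replicate 1, and 16.8% and 16.9% for replicate 2. The stroma-higher IDs held 8.03% and 7.10% for replicate 1, and 8.62% and 9.05% for replicate 2.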

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

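Added after the data were seen were raw library sizes, both covariates, the 6 numbered libraries without a block, and the averaged contrasts. The 0 calls between knockout and wild type, in suspension cells, in stroma cells, in their interaction and averaged over the fractions, stayed at 0 under every alternative run. Few 2-fold changes were recovered from counts simulated with 2 libraries per group and the spread of the model without a block. Stroma against suspension was called under every alternative run, but its count moved. Leaving out one library each gave 345 to 1708 IDs in wild type (1556 with all libraries), 386 to 1555 in the knockout (1638) and 2143 to 3070 averaged over the genotypes (3284), where fits with a single library in a group assume that it varies like the other groups. Without a low-count filter 2367 IDs were called in wild type, and the cause was not tested.

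Deviations from group means correlated across IDs between libraries of the same replicate number at 0.70 for wild-type and knockout suspension, 0.42 for wild-type suspension and wild-type stroma, and 0.38 for knockout suspension and wild-type stroma. These are 2 numbers only, and the labels do not say what a number marks, so this is a hint from the data and not a pairing by design. With the replicate block on the 6 numbered libraries, 0 IDs were called between the genotypes in suspension and 3479 between the fractions in wild type, against 0 and 1351 in the same libraries without it. Between the genotypes, 279 and 49 IDs had an unadjusted p under 0.05 with and without it. The 3479 included all 1556 of the model without a block. With the replicate block by number on the 4 wild-type libraries alone, 3506 were called. No paired analysis was possible for the genotypes in stroma, the interaction and the fractions of the knockout. The knockout stroma columns share one header and cannot be matched to a replicate number.

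With the first residual component as a covariate, the fraction counts were 3671 in wild type, 3546 in the knockout and 5107 averaged. That covariate was taken from the same counts, so its p-values are too small. With 1 surrogate variable they were 1280, 1404 and 2599. Each of the 4 named IDs kept its direction under every alternative run, and uc009gyq.2 and uc008wmr.1 also kept their calls. Not run, because the sources used here gave no names for the IDs, were the removal of globin and ribosomal protein genes, the gene list tests and the check of Dnmt2.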

Other observations

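The tests of library depth, of abundant IDs, of shared preparation, of the set correlation, of stroma cells in the suspension libraries, and of the splits by replicate number and by genotype were chosen after the results were seen, as were the averaged contrasts and the sets of IDs far apart between the fractions. Averaged over both genotypes, edgeR's quasi-likelihood test called 1708 IDs higher and 1576 lower in stroma, together 3284, of which 377 and 369 changed more than 4-fold. The count was 2143 without wild-type stroma replicate 2 and 2145 without knockout stroma library b, and stroma-higher IDs made up 52.0% of the calls with TMM scaling and 34.2% with raw library sizes. In a fit with only 2 groups of 4 libraries, 4127 IDs separated the fractions. Of the 35 splits of the 8 libraries into 4 and 4, 1 called as many, the real one. The highest other split called 103. All other splits left the fraction difference in the spread of the fit, which lowers their calls. With the fractions in the model, the split that called 103 called 2878. The splits therefore cannot decide whether a chance split would call as many.

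Averaged over both fractions, edgeR called 0 IDs between knockout and wild type. An unadjusted p under 0.05 was reached by 62, against 508 for uniformly spread p-values. DESeq2 and limma with voom called 0 as well, with 19 and 55 at that level. The 95% interval of this average lay within 2-fold for 8004 IDs (78.8%). As the real count was 0, all 18 splits that part the libraries of each fraction 2 against 2 had to call as many, so they say nothing on chance, and 18 splits are too few for a share under 0.05. The highest other split called 2878 IDs. It set the 3 libraries numbered 1 and knockout stroma library a against the rest, which points to a structure of the samples other than genotype.

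Libraries of one replicate number shared a profile across groups, with 908 IDs higher and 1060 lower in number 1 than in number 2 over the 3 numbered groups, together 1968. Of the 4 ways to part these libraries, 1 called as many, the labelled one, and the highest other called 0, but 4 splits are too few for a share under 0.05. The other splits also left the number difference in the spread of the fit, which lowers their calls. They therefore cannot decide whether a chance split would call as many. Library depth is argued against, since number 1 was the deeper library in both suspension groups and the shallower one in wild-type stroma, yet the number differences of suspension and wild-type stroma correlated across IDs at 0.436. A few abundant IDs taking more counts would shift the others one way, but with raw library sizes 49.0% of the calls among the IDs other than the 100 most abundant went in the less frequent direction, and the correlation of 0.462 over the 5363 IDs with about equal levels in both fractions (log2 fold change within 0.5) argues against unequal mixing of the fractions. A shared day or batch of preparation and a difference between animals or cultures cannot be told apart, as 0 sample labels say what a number marks.

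The 377 IDs far higher in stroma tended to be lower in knockout than in wild-type suspension cells, with a median log2 fold change of -0.16 and 248 of the 377 below 0, but the genotypes were not separated for any of these IDs by edgeR. With a preset correlation of 0.01, limma's camera gave the set an adjusted p of 4.14e-06 over 4 tests, while with the correlation estimated at 0.238 the unadjusted p was 0.335 and the adjusted p 0.671, so the low value may rest on the preset correlation. Stroma cells carried into both wild-type suspension libraries are a hypothesis that would lower the set for both replicate numbers. The median log2 difference was -0.39 for number 1 and 0.11 for number 2. The value for number 2 met the bound set against this hypothesis (above 0) but lay within its spread of 0.20. That spread was added to the test after the median was seen, so the hypothesis stays open. Stroma cells carried into a single library need lower the set for its number only, so this test cannot count against that. An effect of genotype stays open too, untested beyond these values.

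The 369 IDs far higher in suspension cells had a median log2 fold change of 0.28 between knockout and wild-type suspension, with 0.43 for replicate 1 and 0.20 for replicate 2. Of the 369, 88 were below 0. Camera gave an adjusted p of 3.54e-21 with the preset correlation and 0.453 with an estimated one. In stroma cells the medians of the stroma-higher and suspension-higher sets between genotypes were -0.02 and 0.05, with adjusted p-values of 0.519 and 0.0349 with the preset correlation, and 0.890 and 0.858 with an estimated one. No camera call between genotypes held with an estimated correlation. That correlation was estimated without replicate number in the model, so the profile shared by number enters it and can raise these p-values. The set tests therefore do not decide whether the sets differed between the genotypes.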
